A study of Mus musculus with 3 samples.

How the data were processed

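Single-nucleus ATAC-seq had been run on GFP-positive nuclei sorted from the dorsal skin of Dct-rtTA; Tre-H2B-GFP mice, in which doxycycline switches on a histone-GFP label in cells that use the Dct promoter. Doxycycline was given for 5 days. The 3 GEO samples were 1 library of telogen mice (12) and anagen mice (8) and 2 technical replicates of a pool of 24 mice exposed to UVB. The treatment text gives the age as 7 weeks and the sample characteristics as 8 weeks. Nuclei had been tagged by combinatorial barcodes on plates, per the labels' protocols.

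The deposited matrices hold whole-number counts per feature and nucleus, 1 matrix per condition, over 315694 shared features of 500 bp. Bowtie2, SAMtools, MACS2 and the mm10 (GRCm38) build are named in the submitters' processing notes, with no version. How counts were made from reads, whether cut sites were shifted for the transposase, which filters were put on nuclei and whether doublets were removed are not given in the sources used here. No count was above 4. The value 2 made up 61.1% of the entries above 0 and the value 1 made up 31.0%, so most counts come in pairs, and intervals that treat each count as independent are too narrow. Barcode names carry a condition and a tag number (telogen 1 to 10, anagen 1 to 8, UVB up to 24) that the labels do not explain. No map of UVB nuclei to the 2 technical replicates was used here, so UVB is 1 sample.

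Many barcodes were second copies of a nucleus under another tag. In telogen and anagen the copies lay between tags a and b of the same tag number, and in UVB between tag numbers. Within a condition, 2 entries sharing over 30% of their open features were taken as 1 nucleus, and the deeper copy was kept. Second copies numbered 543 in telogen (21.0%), 1721 in anagen (31.4%) and 61 in UVB (0.922%), with median overlaps of 97.2%, 89.95% and 97.52%. The 506 barcodes seen in more than 1 condition had a median overlap of 3.28% and were kept. The design fixed before the data were examined named all deposited nuclei; counting each nucleus once departs from it, was chosen after seeing the data, and the alternative with second copies is given in the closing section. This left 2042 telogen, 3753 anagen and 6554 UVB nuclei.

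Features open in at least 20 nuclei and outside the top 1% were weighted by TF-IDF (165102 features) and reduced to 30 components, 1 of which was left out for its correlation with depth. A graph of 15 nearest neighbours was clustered by the Leiden method at resolution 0.6 with seed 1. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. Clusters were named from marker lists fixed before the data were examined: melanocyte, keratinocyte, fibroblast, myeloid and Langerhans, T cell, endothelial, Schwann, pericyte and smooth muscle, skeletal muscle and adipocyte. A name needed at least 3 markers at 2-fold or more, the highest median fold of all lists, and no other class with more markers among the top 10 genes by fold (genes with at least 200 counts). The lists' scores had been seen when this rule was settled, and a rule that also needs a lead of 0.3 (log2) over the next list was tried. Cluster 6 met the first rule as pericyte and smooth muscle but lost that name under the second, with no pericyte marker among its top 10 genes by fold, so it is given by its number, a choice made after seeing the data. No doublet caller was run; nuclei above 3 times the median count of their condition were left out in an alternative.

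Gene positions came from the RefSeq annotation of GRCm38.p6, which gives no strand in the table used here. A gene's counts were therefore summed over features overlapping the gene body and 2 kb at both ends, in place of the 2 kb upstream written in the design, and features within 1 kb of either gene end stood for gene starts. Of 21631 protein-coding genes, 18019 had a feature, and 3.69% of features lay in more than 1 gene window. Of 310 list and marker genes, 308 were matched (all but Mx1 and Trdc).

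Each condition is 1 sample, so no test, p-value or standard error was computed between conditions. Counts were summed over the nuclei of a class and expressed as CPM, over the counts in features. Ratios have exact conditional binomial 95% intervals and shares have Clopper-Pearson 95% intervals, both for counting error only. A gene or feature at 0 in a condition was set to a floor of 3 counts over that condition, and its ratio is given at that floor. The end of its 95% interval lies nearer to 1 than the ratio at the floor. A gene list is described by the median log2 ratio of its members with at least 30 counts and by that median's percentile among 10000 random lists of the same size matched on mean count in 20 bins. On simulated counts, the intervals held the simulated value for 85.3% of 10487 unchanged genes in anagen over telogen, 85.0% of 11018 in UVB over telogen and 83.6% of 12603 in UVB over anagen. Single unchanged genes gave intervals as far from 1 as a lower end of 3.89 or an upper end of 0.421 in anagen over telogen, 3.96 or 0.400 in UVB over telogen, and 1.81 or 0.571 in UVB over anagen. Simulated 4-fold changes were found for 100% of 69, 80 and 90 genes in these comparisons, and 2-fold changes for 78.8% of 85, 77.2% of 92 and 99.0% of 97 genes.

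The named genes were chosen by a rule fixed before the data were examined: in melanocyte-like nuclei, the 10 highest and 10 lowest protein-coding genes with at least 100 counts over both conditions and a gene-end ratio in the same direction over at least 10 counts, ranked by the end of the interval nearest to 1. Features were the 5 highest and 5 lowest with at least 30 counts. The fixed gene lists were pigment synthesis and melanosome, melanocyte lineage regulators, stem cell maintenance, Wnt signalling, cell cycle, p53 and DNA damage, interferon and antigen presentation, immediate early and AP-1, cAMP and MC1R signalling, NRF2 and oxidative stress, migration with adhesion and matrix, and a housekeeping control. Members of these lists could be named with their values. Some genes that the rule takes are not reported here. The alternatives changed the gene window, the scaling, the weight of deep nuclei, the depth filter, the list minimum, the population and the clustering. Thinning to 1000 counts left out shallower nuclei and kept 160 of 226 telogen, 958 of 1116 anagen and 2496 of 2935 UVB melanocyte-like nuclei. Motifs were not analysed here because no genome sequence was used.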

Results

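Chromatin accessibility was compared between melanocyte-lineage nuclei of resting skin and of skin in which the lineage is activated, by hair growth or by UVB. The assay was single-nucleus ATAC-seq, in which a transposase cuts and tags open DNA. Nuclei carrying a doxycycline-induced histone-GFP label driven from the Dct promoter were sorted from the dorsal skin of mice in telogen, the resting phase of the hair cycle (12 mice), in anagen, the growth phase started here by chemical depilation (8 mice), and after 3 exposures to UVB at 2.2 mJ/cm2 (24 mice). Counted once, the data held 2042 telogen, 3753 anagen and 6554 UVB nuclei with 5225945, 10397896 and 16183702 counts. Median counts per nucleus were 1650, 1577 and 1726 over all nuclei and 1366.5, 2353 and 1696 in the melanocyte-like nuclei compared below. By tag number, the telogen median went down stepwise from 15216 in tag number 1 to 871 in tag number 7. Each condition was 1 sample, so no difference below has a replicate check, and intervals cover counting error only. Telogen and anagen shared a library while UVB was in others, so UVB and library cannot be told apart. Among unchanged simulated genes, 14.7% of intervals in anagen over telogen, 14.99% in UVB over telogen and 16.4% in UVB over anagen lay off 1, which sets a floor for the counts of list members given here.

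Melanocyte-like nuclei made up 11.1% of telogen nuclei (226 nuclei, 95% interval 9.74% to 12.5%), 29.7% of anagen nuclei (1116 nuclei, 28.3% to 31.2%) and 44.8% of UVB nuclei (2935 nuclei, 43.6% to 46.0%). Endothelial-like nuclei made up 30.2% in telogen, 22.5% in anagen and 6.74% in UVB. Keratinocyte-like nuclei made up 21.7%, 8.87% and 22.3%, and myeloid-like nuclei 17.9%, 4.08% and 5.00%. Fibroblast-like nuclei held 9.94%, 13.4% and 12.0%, and Schwann-like nuclei 3.62%, 2.80% and 7.06%. Cluster 6, left without a name because pericyte and smooth muscle markers (median log2 fold 1.50) and fibroblast markers (1.21) were both high in it, held 5.58%, 18.7% and 2.09%. No cluster was named for T cells, skeletal muscle or adipocytes. Nuclei had been sorted for GFP, so these shares describe the sort and not the skin.

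The melanocyte-like share differed widely between tag numbers. Over tag numbers with at least 50 nuclei its median was 9.89% in telogen (range 0% to 20%, 10 tag numbers), 37.7% in anagen (17.1% to 65.0%, 7 tag numbers) and 59.7% in UVB (13.7% to 74.3%, 15 tag numbers). UVB tag number 19 held 2934 nuclei, of which 24.2% were melanocyte-like, against 61.5% of the other UVB nuclei. With another clustering seed (3) the shares were 7.05%, 25.5% and 30.9%. With telogen and anagen clustered without UVB, they were 0.147% (3 nuclei) in telogen and 19.2% in anagen.

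**Figure D1:**
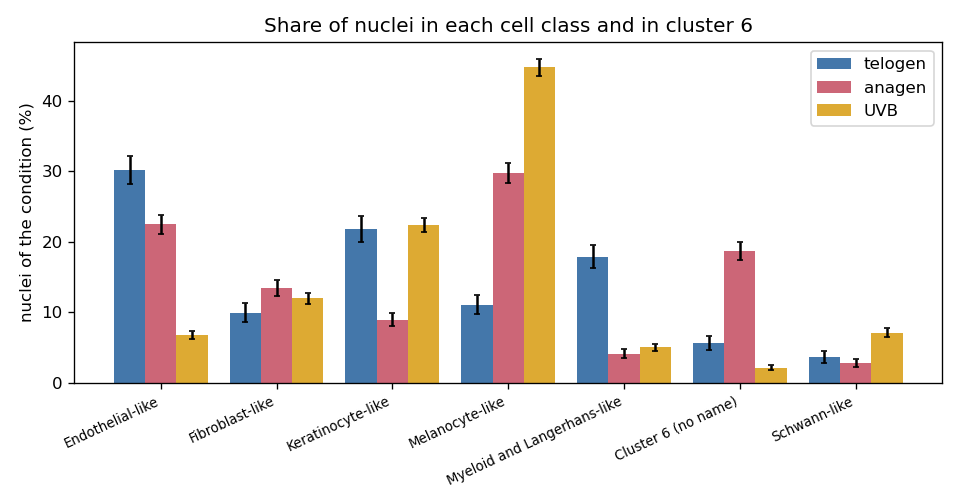
Share of nuclei (%) in each named cell class and in cluster 6, for telogen (blue), anagen (red) and UVB (yellow), with exact binomial 95% intervals for counting error as error bars. The melanocyte-like bars stand at 11.1%, 29.7% and 44.8%, and the endothelial-like bars at 30.2%, 22.5% and 6.74%.

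Within each condition the melanocyte-like nuclei were set apart by pigment-cell genes, the markers from which they were named. Dct, which encodes dopachrome tautomerase of melanin synthesis, was 15.3-fold higher in melanocyte-like than in other telogen nuclei (95% interval 13.01 to 18.1), 9.78-fold in anagen and 7.18-fold in UVB. Mlana, a melanosome gene, was 35.3-fold, 25.9-fold and 15.2-fold higher. Pax3, a transcription factor of the lineage, was 13.8-fold, 14.2-fold and 6.54-fold higher. Some markers stood out less. Pmel was only 1.91-fold, 2.34-fold and 2.31-fold higher, and Trpm1 1.98-fold, 6.07-fold and 2.01-fold. Oca2 was 2.84-fold and 8.53-fold higher in telogen and anagen but 1.18-fold in UVB (1.02 to 1.36). In cluster 3, 6 of 13 melanocyte markers were at 2-fold or more. The class joined clusters 1, 3 and 8. Cluster 8 held 68.7% of the melanocyte-like nuclei of anagen, 2.21% of those of telogen and 1.36% of those of UVB, and clusters 1 and 3 held the rest. With 1 sample per condition, cluster 8 cannot be told apart from the anagen preparation. Re-clustering this class gave 3 sub-clusters; sub-cluster 3, with Slc24a4, Helz, Nt5c3b and Oca2 among its top 10 genes by fold, held 70.0% of anagen (67.2% to 72.7%), 7.08% of telogen and 2.73% of UVB melanocyte-like nuclei.

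Genes of pigment synthesis and the melanosome were more open in anagen than in telogen melanocyte-like nuclei. Of the 18 list members, 10 had an interval above 1, 0 had one below 1 and 8 intervals held 1; the list median was 0.76 on the log2 scale (0.57 to 1.10) at percentile 98.3 of matched random lists. Slc24a5, a melanosome ion exchanger, was 6.20-fold higher (2.83 to 16.98), Oca2, a melanosome membrane protein, 4.55-fold (3.16 to 6.81), Trpm1 4.38-fold (3.41 to 5.73) and Tyr, the tyrosinase that limits melanin synthesis, 3.23-fold (2.10 to 5.24). Dct had a ratio of 0.990 (0.881 to 1.12) and Slc7a11 of 0.932 (0.569 to 1.63). Much of the Dct signal lay in 1 feature at the Dct start (chr 14, 118052265 to 118052765). It held 1771 of 4222 anagen counts, and 34 and 208 of 306 telogen counts in tag numbers 1 to 7 and 8 to 10. Its level differed within telogen, at 300 CPM in tag numbers 1 to 7 and 910 in 8 to 10. The feature took a larger part of the telogen than of the anagen Dct counts. Outside it, Dct had more CPM in anagen than in telogen, so the ratio near 1 rests on this feature. The telogen class rested on clustering together with UVB, without which only 3 of its 226 nuclei were called melanocyte-like. Cluster 8 held most anagen nuclei of this class, and in clusters 1 and 3 alone the list median was 0.14. Over gene ends it was 0.22, and over all nuclei, where the melanocyte-like share differs, 1.94.

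Lineage regulators had a median of 0.63 in the same comparison, at percentile 93.7, with 10 members above 1, 2 below and 4 holding 1. The melanocortin receptor Mc1r was 3.17-fold higher (1.91 to 5.69), the receptor tyrosine kinase Kit 2.15-fold (1.73 to 2.70) and Sox10 1.76-fold (1.27 to 2.502). Mitf, the master regulator of the lineage, had a ratio of 0.974 (0.847 to 1.12), and Tfap2b was lower, at 0.391 (0.278 to 0.562). This list's median was 0.17 in clusters 1 and 3, 0.27 over gene ends, 0.28 against telogen tag numbers 8 to 10 and 0.35 in thinned nuclei.

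Immediate early and AP-1 genes, which code for quickly induced transcription factors, were less open in anagen than in telogen melanocyte-like nuclei. Their list had a median of −0.49 (−0.59 to −0.29) at percentile 0.03, with 12 of 18 members below 1, 1 above and 5 holding 1. Jund had a ratio of 0.430 (0.359 to 0.520), Atf3 of 0.409 (0.325 to 0.520) and Nr4a2 of 0.405 (0.326 to 0.508); Dusp1, a phosphatase, was higher, at 1.57 (1.12 to 2.25). Counts within 1 kb of a gene end made up 44.3% of telogen counts in these nuclei (44.1% to 44.5%), 36.6% of anagen counts (36.5% to 36.6%) and 44.1% of UVB counts (44.07% to 44.1%). With housekeeping gene ends as the scale the list median was −0.17, in clusters 1 and 3 it was −0.12, and in thinned nuclei −0.32.

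The other lists lay within the central 95% of the random lists in anagen over telogen. Their medians were −0.37 for interferon and antigen presentation genes (percentile 4.215), 0.28 for Wnt signalling (82.9), 0.11 for cAMP and MC1R signalling (31.1), 0.08 for p53 and DNA damage (58.5) and −0.02 for stem cell maintenance (22.5). They were −0.03 for the cell cycle (34.7), −0.09 for NRF2 and oxidative stress (26.1), −0.07 for migration, adhesion and matrix (14.8) and −0.22 for the housekeeping control (12.8). Over gene ends cAMP and MC1R signalling turned to −0.26, and stem cell maintenance and NRF2 stood at −0.39 and −0.33. In clusters 1 and 3 Wnt signalling turned to −0.22. Over all nuclei p53 and DNA damage turned to −0.29, stem cell maintenance to 0.02, NRF2 and oxidative stress to 0.05 and migration, adhesion and matrix to 0.14. The median of all genes was 0.06.

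**Figure D2:**
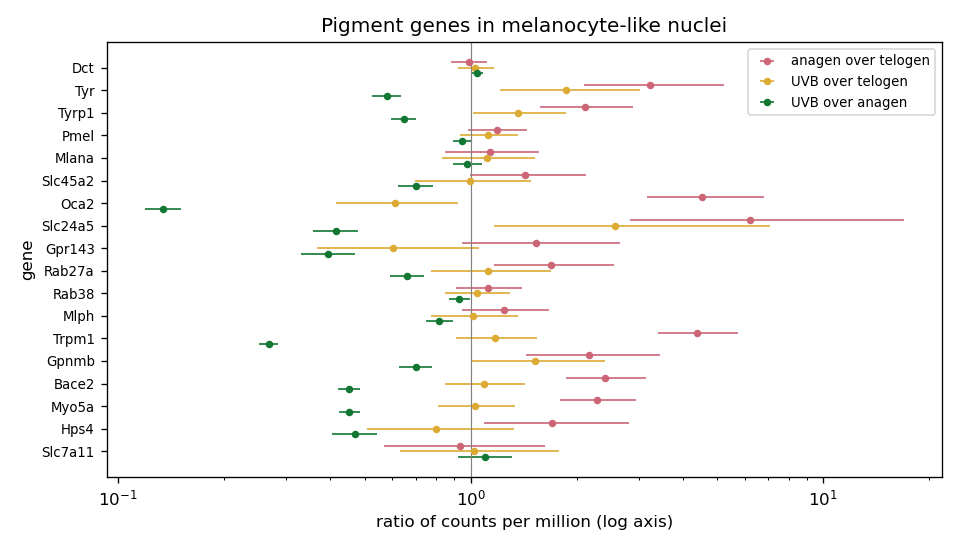
Ratios of CPM (log axis) of the 18 pigment genes in melanocyte-like nuclei, anagen over telogen (red), UVB over telogen (yellow) and UVB over anagen (green), with exact 95% intervals for counting error as lines. Oca2 stands at 4.55, 0.609 and 0.134. Dct stands near 1 in all 3, with much of its signal in 1 feature at the Dct start. Outside that feature, Dct was higher in anagen than in telogen or UVB.

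Among single genes of melanocyte-like nuclei, the solute carrier Slc24a4 was 12.96-fold higher in anagen (6.81 to 28.4; chr 12, 102128727 to 102267133), the laminin gene Lama1 19.01-fold (5.24 to 157; 2 telogen counts), the creatine transporter gene Slc6a8 29.3-fold (5.22 to 1159; 1 telogen count) and the phosphodiesterase gene Pde8a 10.6-fold (4.86 to 29.0). Rbpms2 (chr 9, 65629356 to 65660536), with 405 anagen and 0 telogen counts, was 9.68-fold higher at the floor of 3 counts (lower end of the interval 7.84). At the same floor L3mbtl2 was 8.44-fold higher (lower end 6.83) and Helz 7.56-fold (6.11). Nt5c3b, Morn4 and Ilkap, also at 0 in telogen, were 7.15-fold, 7.08-fold and 6.41-fold higher at the floor (lower ends 5.78, 5.72 and 5.18). The 10 lowest genes were Pcdh9 with a ratio of 0.180 (0.135 to 0.244), Gli2, a Hedgehog transcription factor, with 0.184 (0.132 to 0.262), Parp8, Myo5b, Lrrtm4, Cacna2d3, Ofcc1, Pde1b, Rhobtb3 and Acot11, all between 0.180 and 0.215. All 20 lay beyond the intervals of unchanged simulated genes. More genes were at 0 in telogen than counting alone gives, 119 against 24.7 expected. Over clusters 1 and 3 alone, Slc24a4 stood at 1.30 on the log2 scale in place of 3.70, Lama1 at 1.85 in place of 4.25 and Acot11 at −0.18 in place of −2.22. Against telogen tag numbers 8 to 10 alone Gli2 turned to 0.27 on the log2 scale, from 5 telogen counts and with an interval that held 0 (−0.99 to 1.92). In clusters 1 and 3 Rbpms2 had 5 anagen and 0 telogen counts, too few to give a direction. Features overlapping a second gene gave 36.1% of the counts of Nt5c3b and 53.7% of those of Pde1b.

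Pigment genes differed little between UVB and telogen melanocyte-like nuclei. The list median was 0.09 (−0.01 to 0.25) at percentile 60.3, with 4 members above 1, 1 below and 13 holding 1. Slc24a5 was 2.57-fold higher (1.17 to 7.07) and Tyr 1.87-fold (1.21 to 3.03), while Oca2 was lower, at 0.609 (0.416 to 0.923). Over all nuclei, where the melanocyte-like share differs, the median was 1.23. With UVB left out of the clustering, only 3 of these 226 telogen nuclei were called melanocyte-like. The telogen class thus rested on clustering together with UVB, so likeness between them may be partly built in.

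No list lay in the outer 2.5% of random lists at either end in UVB over telogen. The p53 and DNA damage genes had a median of 0.28 (percentile 96.8), with 5 of 20 members above 1, 0 below and 15 holding 1; Ccng1, a p53 target, was 3.42-fold higher (1.56 to 9.37) and Rrm2b, a ribonucleotide reductase subunit, 1.76-fold (1.13 to 2.91). The immediate early and AP-1 genes had a median of 0.23 (percentile 95.1), with 5 of 18 above 1, 0 below and 13 holding 1; Klf4 was 2.06-fold higher (1.41 to 3.15) and Fos 1.41-fold (1.08 to 1.87). Lineage regulators stood at 0.20 (percentile 86.4), interferon genes at 0.18 (83.5), cell cycle at 0.13 (80.5), cAMP and MC1R signalling at 0.11 (73.2) and migration, adhesion and matrix at 0.09 (59.5). Wnt signalling stood at 0.04 (57.5), NRF2 and oxidative stress at 0.03 (44.3), stem cell maintenance at −0.07 (14.8) and the housekeeping control at 0.01 (38.7). Over all nuclei the p53, immediate early and interferon medians turned to −0.16, −0.19 and −0.21. Over gene ends Wnt signalling stood at 0.44, lineage regulators at 0.36 and cAMP and MC1R signalling at −0.17, and against telogen tag numbers 8 to 10 lineage regulators turned to −0.12.

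The 10 highest genes in UVB over telogen, Ilkap, Snapc1, BC004004, Ccdc38, Secisbp2, Iqce, Recql5, Fkbp8, Cdo1 and Polr1a, were all at 0 in telogen. Among all genes, 81 were at 0 in telogen against 58.2 expected from counting alone. At the floor of 3 counts these 10 were 2.91- to 4.58-fold higher. Their lower ends, at most 3.70, lay within what unchanged simulated genes gave. Over all nuclei, 8 of these 10 had ratios below 1, of which only those of Recql5, Fkbp8 and Polr1a had intervals below 1. Myh6, a cardiac myosin gene, was lowest with a ratio of 0.00931 (0.00614 to 0.0137). It was followed by Fgd5 at 0.209 (0.134 to 0.339), Lrrtm4 at 0.210 (0.150 to 0.2998), Rspo3, which codes for a Wnt agonist, at 0.233 (0.150 to 0.375), Galnt17 at 0.234 (0.149 to 0.380) and Gli2 at 0.284 (0.209 to 0.393). Tox, Parp8, Dach1 and Dpyd, between 0.266 and 0.3003, lay within the simulated range. Against telogen tag numbers 8 to 10 alone Gli2 and Fgd5 turned to 0.89 and 0.22 on the log2 scale, from 5 and 3 telogen counts and with intervals that held 0, Rspo3 stood at −0.36 in place of −2.10, and over all nuclei Galnt17 turned to 0.89.

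Pigment genes were less open in UVB than in anagen melanocyte-like nuclei. Of 18 members, 14 had an interval below 1, 1 above and 3 held 1, with a median of −0.62 (−0.71 to −0.55) at percentile 0.04. Oca2 had a ratio of 0.134 (0.119 to 0.150), Trpm1 of 0.268 (0.251 to 0.285), Tyr of 0.577 (0.524 to 0.636) and Dct of 1.04 (1.00 to 1.09). The feature at the Dct start held 4510 of 5974 UVB and 1771 of 4222 anagen counts of Dct, so that ratio depends much on it. Outside this feature, Dct had fewer CPM in UVB than in anagen. Lineage regulators stood at −0.35 (percentile 4.35), with Mc1r at 0.455 and Kit at 0.533; that median turned to 0.17 over gene ends and to 0.096 in clusters 1 and 3. In clusters 1 and 3 alone, which leave out the cluster with most anagen nuclei, the pigment median was −0.060; over gene ends it was −0.28.

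The immediate early, interferon and cell cycle lists had higher medians in UVB than in anagen. The housekeeping control moved the same way but less, to 0.27 (percentile 84.9), with 7 of 13 members above 1, 1 below and 5 holding 1. The immediate early and AP-1 list had a median of 0.75 (0.67 to 0.81) at percentile 100, with 15 of 18 members above 1, 1 below and 2 holding 1; Atf3 was 2.51-fold higher (2.27 to 2.78) and Jund 2.24-fold (2.06 to 2.42). The interferon and antigen presentation list had a median of 0.65 (0.56 to 0.81) at percentile 100, with 16 of 20 above 1, 0 below and 4 holding 1; Ifih1, a sensor of viral RNA, was 3.30-fold higher (2.45 to 4.52) and Irf1 3.00-fold (2.42 to 3.75). The cell cycle list stood at 0.45 (0.16 to 0.57) at percentile 99.9, with 11 of 21 above 1, 5 below and 5 holding 1; Mcm6 was 2.00-fold and Cdk1 1.68-fold higher, while E2f8, Aurka and Bub1 were lower, at 0.604, 0.484 and 0.415. In clusters 1 and 3 alone the medians were 0.31, 0.27 and 0.01, over all nuclei 0.23, 0.19 and 0.32, and with housekeeping gene ends as the scale 0.47, 0.37 and 0.17; the thinned cell cycle median was 0.22.

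The remaining lists in UVB over anagen stood at 0.34 for migration, adhesion and matrix (percentile 96.0), 0.27 for the housekeeping control (84.9), 0.25 for p53 and DNA damage (90.7) and 0.10 for stem cell maintenance (68.9). NRF2 and oxidative stress stood at 0.05 (53.2), Wnt signalling at −0.10 (19.2) and cAMP and MC1R signalling at −0.13 (27.4). Over gene ends cAMP and MC1R signalling turned to 0.096, and stem cell maintenance and NRF2 stood at 0.40 and 0.22. With housekeeping gene ends as the scale p53 and DNA damage turned to −0.03, stem cell maintenance to −0.19 and NRF2 to −0.23. The median of all genes was −0.05.

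Among single genes, the epidermal regulator Trp63 was 6.78-fold higher in UVB than in anagen melanocyte-like nuclei (5.01 to 9.36; chr 16, 25683763 to 25892088), the tight-junction gene Cldn1 7.43-fold (4.96 to 11.6) and the urate transporter gene Slc2a9 5.68-fold (4.84 to 6.70). Gucy1a1, Tpbg, Clvs1, Sec16b and P3h2 were 5.01- to 5.92-fold higher. Trp63 is a marker of keratinocytes, whose share of nuclei was 8.87% in anagen and 22.3% in UVB. Lowest were Myh7 at 0.00767 (0.00307 to 0.0159) and Myh6 at 0.0186 (0.0126 to 0.0266), followed by Tmem151a, Slc16a4, Unc13d, Tagap, Tmem269, Slc24a4 at 0.112 (0.0980 to 0.129), Nt5c3b and Oca2, all between 0.0724 and 0.134. All of these lay beyond the simulated range of unchanged genes. In clusters 1 and 3 Slc24a4 moved from −3.15 to −0.99 on the log2 scale, Oca2 from −2.90 to −1.06 and Trp63 from 2.76 to 1.54. Unc13d shared 89.5% of its counts with a second gene, Myh7 73.7% and Myh6 40.3%.

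The Myh6 and Myh7 ratios rested on a block of 9 features at these neighbouring cardiac myosin genes (chr 14, 54965390 to 54970814). The block took in 1 end of Myh6, which reaches to 54968017, the gap between the genes, and the edge of Myh7, which begins at 54970684. A count in the block was found in 33.3% of anagen nuclei (31.8% to 34.8%), 29.3% of nuclei of telogen tag numbers 8 to 10 (26.7% to 32.04%), 0.219% of those of telogen tag numbers 1 to 7 (0.0266% to 0.790%) and 0.565% of UVB nuclei (0.398% to 0.777%). UVB tag number 7, with 51 nuclei, stood apart from the rest of UVB at 37.3% (24.1% to 51.9%). Of its nuclei, 14, 18 and 15 were also deposited under UVB tag numbers 1, 2 and 3. Keeping the deeper copy placed them under tag number 7, so the signal belongs to those tag numbers as well. Of the 5 features lowest in UVB over telogen, 3 lay in this block, as did 3 of the 5 lowest in UVB over anagen.

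**Figure D3:**
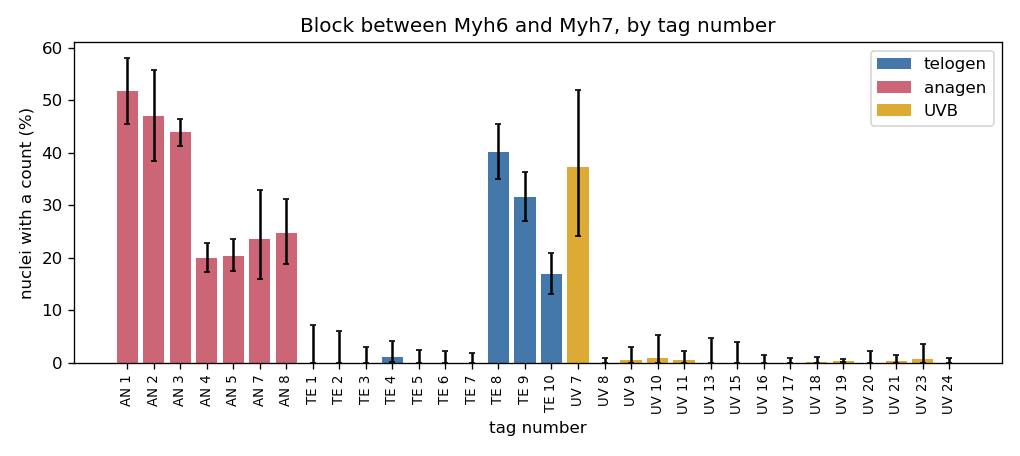
Share of nuclei (%) with a count in the block over the end of Myh6 and the gap to Myh7, by tag number (AN anagen, TE telogen, UV UVB, tag numbers with at least 50 nuclei), with exact binomial 95% intervals as error bars. Telogen tag numbers 8 to 10 and UVB tag number 7 stand with anagen, apart from the other telogen and UVB tag numbers shown. Most nuclei of UVB tag number 7 were also deposited under UVB tag numbers 1 to 3.

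Over all nuclei, single genes ranked in the same way came from several classes. Slc24a5 was 14.8-fold higher in anagen than in telogen (9.41 to 24.8) and Tyrp1 7.75-fold (6.28 to 9.68), beside melanocyte-like shares of 29.7% and 11.1%. The epidermal differentiation genes Krtdap and Casp14 had ratios of 0.0213 (0.0101 to 0.0399) and 0.0633 (0.0365 to 0.104), beside keratinocyte-like shares of 8.87% and 21.7%. Both are among the top 10 genes by fold of keratinocyte-like cluster 4, which held 60 anagen and 263 telogen nuclei, and within keratinocyte-like nuclei the Krtdap ratio was 0.0537 (0.0145 to 0.139). In UVB over telogen the endothelial gene She had a ratio of 0.156 (0.127 to 0.190) and the leukocyte gene Laptm5 of 0.154 (0.124 to 0.191), beside endothelial-like shares of 6.74% and 30.2% and myeloid-like shares of 5.00% and 17.9%.

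Among single 500-bp features away from the block, distances are to the nearest gene end, so that a feature may lie inside a gene body. In anagen over telogen the highest was a feature on chr 5 (38241059 to 38241559), 7003 bp from the nearest gene end, that of Lyar. It was 5.88-fold higher at the floor (lower end 4.75). The lowest was a feature on chr 16 (50615375 to 50615875), 24471 bp from Ccdc54, with a ratio of 0.0209 (0.00761 to 0.0500). In UVB over telogen the highest lay on chr 8 (26756325 to 26756825), 220761 bp from Zfp703, and was 4.99-fold higher at the floor (lower end 4.03). In UVB over anagen the highest lay on chr 18 (45502102 to 45502602), 183535 bp from Kcnn2, and was 22.1-fold higher at the floor (lower end 17.6).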

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

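The tests of another cluster, of muscle nuclei, of extra copies of the Myh6 block and of extra copies of the Dct start region were chosen only after the results were seen. No sample stood far from its group by a test, since each condition is 1 sample.

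Second copies of nuclei drew attention because they are signal that the comparisons leave out. They numbered 543 in telogen, 1721 in anagen and 61 in UVB, and a nucleus and its copy shared a median of 97.2%, 89.95% and 97.52% of open features.

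Pigment genes were more open in anagen than in telogen melanocyte-like nuclei, with a list median of 0.76 on the log2 scale. A greater weight of deep anagen nuclei is argued against, since the median was 0.83 in the 160 telogen and 958 anagen nuclei with at least 1000 counts, each thinned to 1000, and 0.66 in the same nuclei unthinned. Thinning cannot decide whether depth set the class or cluster of a nucleus, because these were taken from unthinned counts. Anagen nuclei had median counts of 3407 in cluster 8, 1637 in cluster 1 and 965 in cluster 3. A single tag number is argued against, since the median was 0.82 without anagen tag number 5, which held the most melanocyte-like nuclei. In clusters 1 and 3 alone the median was 0.14, but this decides nothing, since the clusters were made from the same counts and cluster 8 was the one most open at Oca2 (9.36-fold). Whether that cluster is a pigment-making state of anagen or a property of its preparation stays open, because the condition and the cluster go together and no other anagen sample was analysed.

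Signal in the block over the end of Myh6 and the gap to Myh7 (chr 14, 54965390 to 54970814) was present in some tag numbers and nearly absent in others. Muscle nuclei in the sort are argued against as the whole source, since the highest share of anagen nuclei with a count in any class was 1.38 times the lowest. That share depends on depth. On the CPM scale the anagen classes were less even, from 290 in melanocyte-like to 1237 in endothelial-like nuclei, though all held signal. Extra copies of this stretch carried by the mice of some tag numbers could give signal in every class, and the lowest anagen class held 217 times the block level of telogen tag numbers 1 to 7. That test cannot separate extra copies from other sources of signal at this place, since the only other feature within 20 kb held 12 counts, too few to show an edge. The labels do not say which mice stand behind a tag number, and no biological explanation was tested.

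The feature at the Dct start (chr 14, 118052265 to 118052765, 269 bp from the gene end) was open in nuclei of other classes. Free melanocyte DNA or barcode collisions may account for it: in UVB, the other pigment gene ends stood in nuclei of other classes at a median level, relative to melanocyte-like nuclei, 1.28 times that of the Dct feature. That list holds broadly open gene ends such as those of Bace2 and Hps4, but Tyr (15.5%), Gpr143 (15.0%) and Slc45a2 (11.9%) also stood near the Dct feature (12.1%). Against it as the whole source, though not excluding it, 4 of the 15 gene ends had intervals below that of the Dct feature: Mlana (5.12%), Slc7a11 (5.32%), Slc24a5 (6.50%) and Tyrp1 (7.64%). Extra copies of the Dct start region in the mice of some tag numbers stay open as well, since the feature's level in nuclei of other classes was 6.03 times higher in telogen tag numbers 8 to 10 than in 1 to 7, and 11.5 times higher in UVB. By genotype the mice carried Dct-rtTA, which is driven from the Dct promoter. Whether that transgene holds this stretch was not tested.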

How the results depend on the processing

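Alternatives that kept second copies of nuclei, took clusters 1 and 3 alone, left out UVB tag number 19 or anagen tag number 5, took telogen tag numbers 8 to 10 or asked for a lead of 0.3 in naming were chosen after seeing the data; the others were fixed before. No paired analysis was possible because each condition is 1 sample and no test was run. Motif alternatives and leaving out a UVB technical replicate were not run. Telogen, with 341815 melanocyte-like counts against 4765592 and 6464769, limits every ratio against it. Of the 36 list medians (12 lists in 3 ratios), 36 stayed within their intervals under median-of-ratios scaling, either other list minimum, the depth minimum and second copies, 16 under housekeeping scaling, 20 over gene ends, 21 in clusters 1 and 3, 22 over all nuclei and 27 when thinned. None of the 6 medians in the outer 2.5% of random lists turned sign under an alternative run for it. Of the 30 others, 10 did over all nuclei, 9 under housekeeping scaling, 8 in clusters 1 and 3, 8 when thinned and 7 over gene ends. Over gene ends lineage regulators in UVB over anagen went from −0.35 to 0.17, and cAMP and MC1R signalling to −0.26 in anagen over telogen, −0.17 in UVB over telogen and 0.096 in UVB over anagen. The pigment median of anagen over telogen (0.76) moved to 0.22 over gene ends, 1.94 over all nuclei and 0.14 in clusters 1 and 3; that of UVB over telogen (0.09) moved to 1.23 over all nuclei; that of UVB over anagen (−0.62) moved to −0.28 over gene ends, −0.90 with housekeeping scaling, −0.52 thinned, −0.53 without deep nuclei and −0.060 in clusters 1 and 3. The melanocyte-like shares of telogen, anagen and UVB (11.1%, 29.7% and 44.8%) moved to 7.05%, 25.5% and 30.9% with seed 3. Telogen stood at 0.147% and anagen at 19.2% when clustered without UVB. The telogen share was 13.4% with second copies and 12.6% in tag numbers 8 to 10. Without deep nuclei, anagen and UVB stood at 24.9% and 47.1%, and with at least 1000 counts at 35.0% and 47.4%. Anagen was 21.6% without tag number 5 and UVB 61.5% without tag number 19. Gene-end shares were 49.2%, 41.9% and 49.0% within 2 kb. Of the 60 named gene ratios, 36 left their intervals in clusters 1 and 3, 36 when thinned and 34 over gene ends. With telogen tag numbers 8 to 10, 26 of 40 left their intervals without turning direction and 3 more turned direction. Over all nuclei 11 turned direction (log2): Gli2 (0.076) and Cacna2d3 (0.080) in anagen over telogen, and in UVB over telogen Ilkap (−0.22), Snapc1 (−0.17), Ccdc38 (−0.16), Secisbp2 (−0.11), Iqce (−0.10), Recql5 (−0.53), Fkbp8 (−0.39), Polr1a (−0.83) and Galnt17 (0.89). With telogen tag numbers 8 to 10, Gli2 turned to 0.27 in anagen over telogen, and Fgd5 to 0.22 and Gli2 to 0.89 in UVB over telogen, from 3 to 5 telogen counts. All nuclei mix classes by construction; for the other changes the cause was not tested.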

Other observations

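Genes of other cell classes differed between conditions as well, on 1 sample each and with no test. Values for other classes were not part of the design fixed before the data were examined. In anagen over telogen, the immediate early and AP-1 list was lower in keratinocyte-like nuclei (median −0.60, percentile 0.09 of random lists, 13 of 18 members below 1 and 0 above), in fibroblast-like nuclei (−0.39, percentile 0, 12 below and 0 above) and in the unnamed cluster 6 (−0.43, percentile 0.01, 11 below and 0 above). In Schwann-like nuclei it stood at −0.33 (percentile 1.04), where 0 of 15 members had an interval below 1 and 1 had one above. It stood at −0.05 in endothelial-like nuclei (percentile 21.1, 3 below and 5 above) and at 0.24 in myeloid-like nuclei (percentile 92.5, 0 below and 3 above). Keratinocyte-like nuclei also had a lower interferon and antigen presentation list (−0.83, percentile 0.03, 9 of 17 below and 2 above), and the phosphatase gene Dusp1 had a ratio of 0.193 there (0.126 to 0.285). Clusters within a class were filled unequally. Of the keratinocyte-like clusters, cluster 4 held 263 telogen, 60 anagen and 832 UVB nuclei, and cluster 5 held 181, 273 and 632. Of the fibroblast-like clusters, cluster 9 held 50, 56 and 547, cluster 11 held 74, 130 and 230, and cluster 12 held 79, 317 and 8. Counts within 1 kb of a gene end made up 42.5% of all telogen counts, 37.7% of anagen and 40.3% of UVB counts.

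In UVB over telogen, the same immediate early list was lower in keratinocyte-like (−0.45, percentile 0.01), fibroblast-like (−0.32, percentile 0) and cluster 6 nuclei (−0.52, percentile 0.035) but higher in myeloid-like nuclei (0.54, percentile 99.99, 11 of 18 members above 1 and 0 below). The fibroblast-like nuclei of UVB were mostly in cluster 9, while those of telogen were spread over clusters 9, 11 and 12. In endothelial-like and Schwann-like nuclei the list stood at −0.04 (percentile 78.3) and 0.07 (44.6). In UVB over anagen, myeloid-like nuclei were more open at the antigen presentation genes Cd74, 2.97-fold (2.11 to 4.27), and H2-Aa, 3.09-fold (1.86 to 5.43), while the interferon and antigen presentation list stood at 0.06 there (percentile 54.6, 2 of 14 members above 1 and 12 holding 1). Pigment and lineage genes were higher than in telogen in some other classes: the pigment list stood at 0.63 in keratinocyte-like nuclei in UVB over telogen (percentile 99.99) and at 1.06 in myeloid-like nuclei in anagen over telogen (percentile 100), and Pax3 was 5.33-fold higher in UVB than in telogen endothelial-like nuclei (3.78 to 7.66). Not all classes shared this: in UVB over telogen the pigment list stood at −0.36 in Schwann-like nuclei (percentile 4.35) and 0.09 in cluster 6 (63.035), and the lineage list at −0.15 in Schwann-like (10.1) and −0.008 in myeloid-like nuclei (48.1).

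Pigment genes by tag number, over melanocyte-like nuclei of tag numbers with at least 20 of them, had a median of 3365 CPM in telogen (3016 to 3800, 3 tag numbers), 5143 in anagen (3731 to 5502, 7 tag numbers) and 3280 in UVB (2819 to 3805, 15 tag numbers). Tag numbers equal the mice in number in anagen (8, under 11 tags) and UVB (24), and in telogen there were 10 tag numbers, 12 tags and 12 mice. The labels do not tie tags to mice. Many nuclei appeared under more than 1 tag, within a tag number in telogen and anagen and across tag numbers in UVB. Whether a tag or a tag number is a mouse therefore stays open, and tag numbers were not used as replicates.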
